A study of synthetic construct and Mus musculus with 4 samples.

How the data were processed

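The values analysed were the deposited counts per gene and barcode, which the authors made from the sequencing reads. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 and counted with STARsolo 2.7.5c, and Seurat 4 was used downstream. The annotation release, the handling of molecular identifiers and the filters behind the counts were not given in the sources used here. The table held 1 count class per library and no gene positions, so chromosome coordinates are not reported. The marker lists, thresholds and most alternatives were chosen before the data were examined.

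Libraries were grouped by tissue as labelled, 1 liver and 1 colon. The liver library held 43898747 counts on 15004445 listed barcodes, of which 61.3% had a count, and the colon library 136588519 counts on 13380619 barcodes, of which 74.7% had a count. Counts of table entries sharing a symbol were summed (116 symbols). Of the marker genes, 3 were found under older symbols by their identifier (Emr1 for Adgre1, Igj for Jchain, Clca3 for Clca1), and 2, Defa30 and Kcnq1ot1, were not listed. The mitochondrially encoded group held 37 genes. The ribosomal protein group, 97 genes, was chosen by symbol prefix, which also takes ribosomal S6 kinase genes.

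For the tissue comparison, counts were summed over all barcodes and divided by the library total to give CPM. Log2 ratios used CPM plus a pseudocount of 1 CPM. Fold ratios had exact 95% binomial intervals, and single CPM values exact Poisson intervals. Low counts were read against a set floor of 3 counts, which is 0.0683 CPM in liver and 0.0220 CPM in colon. This floor is not a bound of those intervals. Genes were counted at a 4-fold ratio and at least 50 CPM in the higher tissue. The text names the 10 genes of highest CPM on each side among these, the members of each list with high CPM, and genes that differ from the rest of their list. The median of each list was ranked among 10000 random lists matched on 20 bins of expression. The 26 lists were pericentral, periportal and general hepatocyte, acute phase and injury, oxidative stress and metallothionein, major urinary proteins, sinusoidal endothelium, macrophage, MHC class II, fibroblast and stellate, cholangiocyte, erythroid, surface colonocyte, goblet and deep crypt secretory, crypt base and cycling, enteroendocrine, tuft, smooth muscle, B and plasma cell, T cell, enteric neuron and glia, vascular endothelium, Paneth cell, nuclear-retained RNA, mitochondrially encoded and ribosomal protein. Alternatives left mitochondrially encoded genes out of the total, scaled by TMM, changed the CPM filter or the pseudocount, or kept barcodes with at least 10 counts. Tested on simulated independent counts with 200 of 2000 genes changed 4-fold, the intervals held the true ratio for 96.5% of changed and 95.5% of unchanged genes. For such counts exact intervals do so by construction, so this checked the calculation only. In the real libraries, counts of 1 gene fell on the same barcode more often than independence gave, so the intervals can be too narrow.

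For co-detection, barcodes with at least 2 counts were grouped by their total, each total up to 100 on its own and then in steps of 1.2-fold. The number of barcodes with both of a pair of lists or genes was divided by the number expected from independence within each group, with exact 95% Poisson intervals. Within a list, both numbers were summed over its pairs of genes. Pairs were tested at 20 or more expected co-detections and counted at ratios of at least 1.25 or at most 0.8. In the liver scan each gene's value was the log2 ratio with the pericentral list minus that with the periportal list, counted at 1, with an exact binomial interval. In the other scans it was the log2 ratio with 1 list, counted at 0.5. The 10 genes of largest value per direction were named, and separately those with at least 100 expected co-detections. Each noise count came from 1 Poisson draw per gene and list around the expectation, so it has a scatter of its own. Such draws overstate the scatter for lists present on many barcodes. Alternatives used no grouping by total, other barcode minima and maxima, products of counts, lists without their most abundant gene, both random parts of the barcodes, and totals without mitochondrially encoded genes. A later test chose scan genes in 1 random part of the barcodes, at a size of at least 1 with the nearer bound of its interval at 0.5 or beyond, and measured them in the other part. Tested on simulated data of 9719 genes with 200 changed 4-fold between regions, the scan gave 100% of changed genes the right sign. It placed 66.5% of them and 0.336% of unchanged genes beyond 1, with medians of 1.03 and −1.05 for an expected size of 1.09. The changed genes were drawn only from genes with more counts than nearly all named scan genes. Recovery at the abundance of the named genes was therefore not measured. Independent simulated lists had a ratio of 0.982 and opposed lists 0.662. The simulated counts fell independently on each barcode, without the excess of same-gene repeats on the real barcodes. The simulation therefore does not calibrate real ratios near 1.

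The 2 array oligonucleotide libraries were not used here. Control and injured liver were not compared, because both mice were in 1 library and no map from barcodes to mice was used. Barcodes over tissue were not selected, because no positions were used, and no doublet caller was run on spots smaller than cells. The unspliced share and the spliced-only counts were not analysed here, because the table held 1 count class. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors (0.924 in liver, 1.08 in colon).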

Results

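Seq-Scope lays a frozen tissue section on an array of DNA-barcoded oligonucleotides that was grown on a sequencing flow cell, so that each captured RNA carries the barcode of a spot smaller than a cell. The series held 4 samples. Of these, 2 were libraries of the array oligonucleotides themselves, which were not analysed here, and the others were 1 cDNA library from mouse liver and 1 from mouse colon. The liver library pooled sections of a male control mouse aged 8 weeks, with floxed Depdc5 and Tsc1, and of a female mouse in which albumin-Cre deleted both genes in hepatocytes and whose liver was described as injured. The colon came from a male mouse aged 8 weeks. No map from barcodes to mice or to positions was used, so control and injured liver were not compared, and each library was 1 sample of its tissue. There were no replicates: every interval below covers counting error alone, taking counts as independent, and tissue, animal and library could not be separated.

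The colon library was about 3 times as deep as the liver library. It held 136588519 counts on 9989889 barcodes with at least 1 count, and the liver library held 43898747 counts on 9192646 such barcodes. The median was 9 counts per barcode in colon (interquartile range 4 to 19) and 3 in liver (2 to 6). Barcodes with 10 or more counts numbered 4750557 in colon and 1184667 in liver. Mitochondrially encoded genes took 12.5% of the counts in both libraries. Alb alone took 7.93% of the liver counts, and the most abundant colon gene, mt-Co1, took 2.40%.

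**Figure D1:**
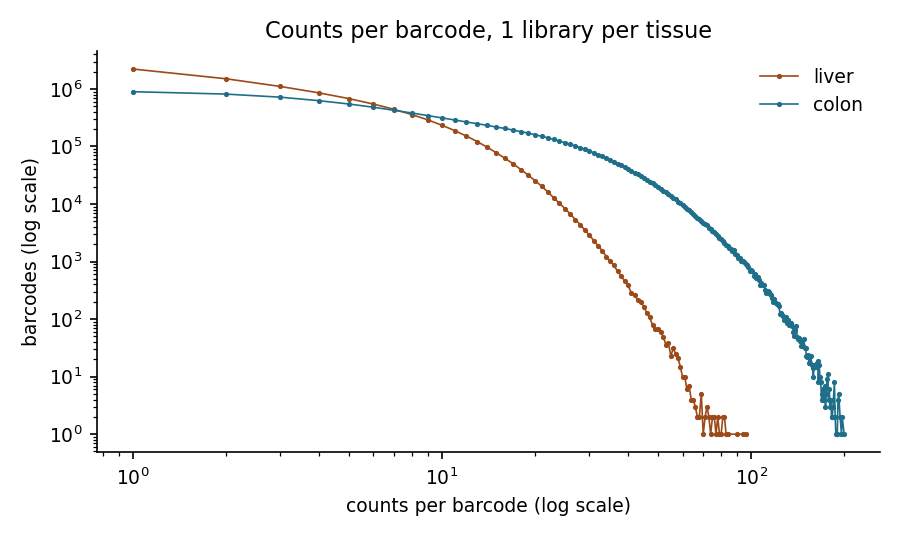
Number of barcodes (vertical axis, log scale) with each count total from 1 to 200 (horizontal axis, log scale) in the liver and colon libraries, 1 library per tissue. The colon curve lies below the liver curve at 1 count, where 897233 colon and 2222545 liver barcodes lie, and above it from 8 counts on.

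The first comparison set the summed colon counts against the summed liver counts, to ask which genes and cell types marked each tissue. A ratio of at least 4 in CPM, the count scaled to the library total, with at least 50 CPM in the higher tissue, was reached by 1254 genes in colon and by 554 genes in liver. The colon genes of highest CPM were Lypd8 (ENSMUSG00000013643), which keeps flagellated bacteria off the surface, at 10434 CPM against 15.3 in liver, and Muc2, the main mucin of intestinal mucus, at 7080 against 77.8 CPM. Lgals4, a lectin of gut epithelium, reached 6525 against 14.2 CPM, Zg16 3920 against 4.87 CPM, and Mptx1 2873 against 3.51 CPM, an 819-fold ratio (95% interval 699 to 966). S100a6 stood at 3057 against 10.8 CPM and the epithelial adhesion gene Epcam at 2962 against 12.1 CPM. Smaller ratios belonged to Actb (4637 against 778 CPM, 5.96-fold), Rplp1 (8.71-fold) and Rpl41 (5.07-fold).

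In liver the first gene was Alb (ENSMUSG00000029368), serum albumin, at 79308 CPM against 66.1 in colon, a 1201-fold ratio (1176 to 1226). Apolipoprotein genes were also among the 10 named: Apoe stood at 20941 against 489 CPM, Apoa2 at 10924 against 12 CPM, Apoa1 at 8097 against 19.9 CPM, and Apoc3 at 7615 against 10.9 CPM. Ttr, the carrier of thyroid hormone and retinol, reached 14315 against 44.2 CPM, and Ahsg 8479 against 7.08 CPM. Mup3, a major urinary protein, had the largest ratio among these, 1825-fold (1694 to 1968). Scd1, the stearoyl-CoA desaturase, reached 8118 against 49.6 CPM. The predicted gene Gm26924 stood at 17347 against 918 CPM. Over the 11502 genes with at least 10 CPM in a tissue, the median log2 ratio of colon to liver was 0.83. After scaling by trimmed mean of M-values (TMM) it was 0.61, so the list values below are read against a general shift. Its size depended on expression: the random lists matched to a list had medians from −0.05 (T cell) to 0.76 (vascular endothelium). The percentiles below take this into account.

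**Figure D2:**
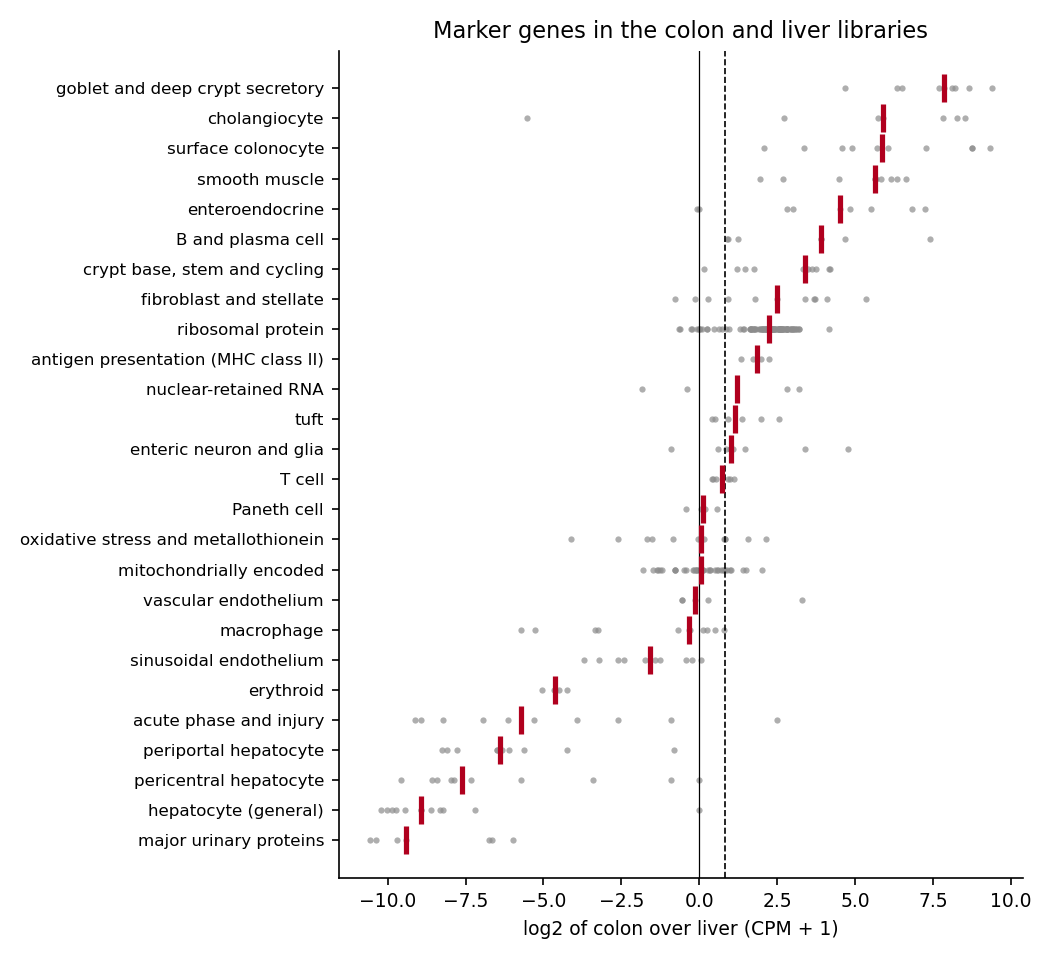
Log2 ratio of colon to liver (CPM + 1) of each marker gene (grey points) and the median of each list (red bars), 1 library per tissue, with a dashed line at the median of 0.83 over genes of at least 10 CPM. Medians run from −9.41 for major urinary proteins to 7.84 for goblet genes.

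Within the lists, genes were counted by the same rule, a 4-fold ratio and at least 50 CPM in the higher tissue. Of 12 general hepatocyte genes, 11 were at least 4-fold higher in liver, and the last, Trf, was listed at 0 in both libraries. Their median log2 ratio of colon to liver was −8.95, below all of 10000 random lists matched on expression. All 7 major urinary protein genes were at least 4-fold higher in liver (median −9.41). Of 10 pericentral hepatocyte genes, which mark the zone around the central vein, 8 were (median −7.60), led by Cyp2e1 at 2508 against 2.26 CPM and Cyp2c29 at 1836 against 4.36 CPM. Of 10 periportal genes 9 were (median −6.41), led by Cyp2f2 at 2636 against 7.69 CPM and by the urea cycle gene Ass1. The acute-phase list had 7 of 10 genes at least 4-fold higher in liver (median −5.73), among them Hamp, the iron hormone hepcidin, at 1716 against 2.53 CPM. Lcn2 and Saa3 were higher in liver without meeting the rule, at 47.7 and 18.4 CPM there. The serum amyloid gene Saa1 was higher in colon, at 1710 CPM against 306 in liver. All 5 erythroid genes were higher in liver (median −4.63). The sinusoidal endothelium list had a median of −1.58, with 2 of 10 genes at least 4-fold higher in liver.

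The goblet, surface colonocyte, smooth muscle, enteroendocrine, B and plasma cell, crypt base, ribosomal protein and cholangiocyte lists lay on the colon side, each above all random lists. The goblet list, secretory cells that make mucus, had 8 of 9 genes at least 4-fold higher in colon (median 7.84), with Fcgbp at 1856 against 7.08 CPM. The surface colonocyte list had 9 of 10 (median 5.87), led after Lypd8 by the carbonic anhydrases Car1 at 1181 against 21.9 CPM and Car4 at 1170 against 1.73 CPM. The smooth muscle list had 9 of 10 (median 5.64), led by Acta2 at 967 against 18.7 CPM and Tpm2 at 711 against 9.09 CPM. For enteroendocrine genes the count was 4 of 9 (median 4.51), with the gut hormone genes Pyy at 286 against 0.888 CPM and Insl5 at 235 against 1.07 CPM. Of 7 B and plasma cell genes, 3 were at least 4-fold higher in colon (median 3.91), led by the antibody gene Igha at 1199 against 6.08 CPM. The crypt base and cycling list had 4 of 10 (median 3.40). Of 97 ribosomal protein genes 90 had a log2 ratio above 0 and 62 were at least 4-fold higher in colon (median 2.25), and the group took 6.64% of the colon counts against 1.13% of the liver counts. The cholangiocyte list, fixed for bile ducts, also holds epithelial genes of gut such as Epcam and Krt19, and 6 of its 7 genes were at least 4-fold higher in colon (median 5.90). The exception was Spp1 at 76.4 CPM in liver and 0.681 in colon.

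Of 11 fibroblast and stellate genes, 6 were at least 4-fold higher in colon (median 2.5, 99.9th percentile of random lists), among them Col3a1 at 719 against 40.7 CPM, and 0 were in liver. The MHC class II genes, which present antigen, were all higher in colon, with a median of 1.85 (91.7th percentile) and Cd74 at 956 against 200 CPM. The macrophage list had a median of −0.34 (2.57th percentile): the shared genes Lyz2, C1qb and C1qc were within 2-fold of each other in the tissues, while the Kupffer cell genes Cd5l (107 against 1.79 CPM) and Clec4f (81.9 against 0.556 CPM) were at least 4-fold higher in liver. The lists of vascular endothelium (median −0.15), tuft cells (1.15), T cells (0.73), enteric neurons and glia (1.03) and nuclear-retained RNA (1.21) had medians between the 10.6th and the 97.9th percentile. The Paneth cell list, a cell type of the small intestine, had a median of 0.12 (85.2th percentile) and summed to 5.71 CPM in colon and 6.15 in liver. The oxidative stress list (median 0.06, 11.95th percentile) and the mitochondrially encoded list (0.05, 14.9th percentile) lay below the general median of 0.83. The medians of their matched random lists were 0.72 and 0.34. Under TMM scaling, which changes the CPM ratio of every gene by the same factor before the pseudocount is added, they stood at −0.17 and −0.12, below the general median of 0.61.

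The genes that check the labels were read once. Xist, transcribed from the inactive X chromosome of females, stood at 54.4 CPM in the liver library, which pooled both sexes (interval 52.3 to 56.6), and at 1.06 CPM (0.896 to 1.249) in the colon library. The Y-linked genes Ddx3y (35.5 CPM in liver, 56.3 in colon), Uty (19.7 and 28.7), Eif2s3y (7.45 and 23.3) and Kdm5d (6.13 and 17.1) were counted in both libraries. The targeted genes were at 16.1 CPM in liver and 16.8 in colon for Depdc5, and at 30.0 and 23.3 for Tsc1. In a pool of both mice, and with tags whose position in the gene is not given, these values check nothing about the deletion.

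The second comparison asked whether genes of a cell type were found on the same barcodes, that is in the same small regions. Within each library the number of barcodes carrying both of a pair of genes was set against the number expected if counts fell independently among barcodes of equal total. Within a list, co-detections were summed over its pairs of genes, so a barcode with several genes counted once for each pair. The intervals treat co-detections as independent, which those of the same barcode are not, so they can be too narrow. In liver, different MHC class II genes had 271 co-detections where 19.7 were expected, a ratio of 13.7 (95% Poisson interval 12.1 to 15.5). Macrophage genes had 497 where 44.8 were expected (11.1, 10.1 to 12.1). Ratios were 7.08 (6.79 to 7.37) for erythroid genes, 5.48 (4.19 to 7.04) for sinusoidal endothelium, 5.07 (3.44 to 7.19) for nuclear-retained RNA and 4.49 (3.62 to 5.51) for fibroblast and stellate genes. The few co-detections of cholangiocyte genes gave 5.76 (2.11 to 12.5), and those of vascular endothelium 2.25 (0.825 to 4.89). Genes of hepatocytes, which fill most of the tissue, were co-detected only a little more than expected: 1.36 (1.33 to 1.40) for pericentral genes, 1.35 for major urinary proteins, 1.23 for acute-phase genes and 1.07 for periportal genes. Near-identical genes such as Saa1 and Saa2 count as pairs in these lists. Neither reads shared between such genes nor differences between the pooled mice were separated. The general hepatocyte, oxidative stress, ribosomal protein and mitochondrially encoded lists lay between 1.03 and 1.04.

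Between liver lists, the strongest pair was macrophage with MHC class II, on 356 barcodes where 72.1 were expected (4.94, 4.44 to 5.48). MHC class II with fibroblast and stellate genes reached 1.54 (1.21 to 1.93). Of 110 liver pairs with at least 20 expected co-detections, 4 passed the upper threshold, 1 of which had an interval that held 1, and 0 had a ratio of 0.8 or less. Pericentral and periportal genes, which mark opposite ends of the lobule, shared 14260 barcodes where 15821 were expected (0.901, 0.887 to 0.916). Pairs that do not contrast the zones had similar or lower ratios, such as pericentral with macrophage (0.900, 0.843 to 0.960), periportal with macrophage (0.905, 0.857 to 0.954) and major urinary proteins with nuclear-retained RNA (0.838, 0.786 to 0.893). Major urinary protein genes shared fewer barcodes with oxidative stress genes than expected (0.857, 0.846 to 0.868), and the latter lay with periportal genes slightly more often than expected (1.07, 1.05 to 1.09). The liver expectation pooled the barcodes of both mice, so genes whose levels differ between the mice give ratios off 1 without any arrangement in space. The ratios of 0.901 and 0.857 rested on the comparison within equal barcode totals: with a single expectation over all barcodes they were 1.23 and 1.197.

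In colon, lists of different cell types were spread nearly independently over the barcodes. Goblet and smooth muscle genes, which belong to different layers of the wall, shared 140901 barcodes where 142320 were expected (0.990, 0.985 to 0.995). Surface colonocyte genes gave 1.00 (1.00 to 1.01) with goblet genes and 0.986 (0.981 to 0.991) with smooth muscle. The pairs of muscle and epithelium turned above 1, to 1.59 and 1.58, with a single expectation over all barcodes. Higher ratios were found for smooth muscle with enteric neurons and glia (1.11, 1.05 to 1.18), with vascular endothelium (1.07, 1.02 to 1.11) and with fibroblasts (1.04, 1.03 to 1.06), and for macrophage with MHC class II (1.11, 1.07 to 1.16). Of 140 colon pairs, 2 passed the upper threshold and 2 had a ratio of 0.8 or less, and all 4 intervals held 1. Within lists, erythroid genes gave 8.10 (5.73 to 11.1) on 38 co-detections and enteric neuron and glia genes 2.40 (1.57 to 3.52) on 26. Plasma cell genes gave 1.54 (1.49 to 1.58), enteroendocrine genes 1.42 (1.33 to 1.53), smooth muscle genes 1.201 (1.19 to 1.22), macrophage genes 1.15 (1.02 to 1.301), MHC class II genes 1.12 and fibroblast genes 1.09. Surface colonocyte (1.04), goblet (1.01), ribosomal protein (1.01) and mitochondrially encoded genes (1.01) lay close to 1. The intervals held 1 for crypt base genes (1.00), tuft cells (0.908), vascular endothelium (1.13) and nuclear-retained RNA (1.06), and T cell and Paneth genes had 0 co-detections with 0.457 and 0.0266 expected.

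**Figure D3:**
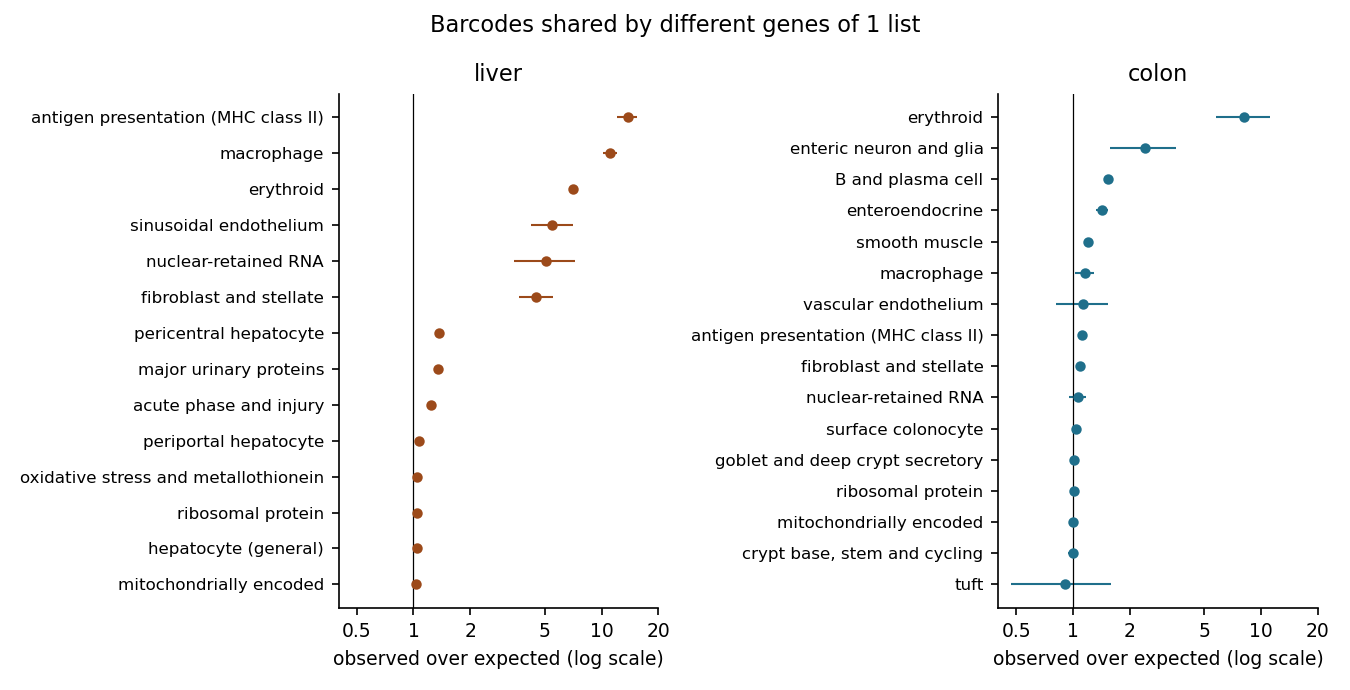
Observed over expected co-detections, summed over the pairs of different genes of a list (horizontal axis, log scale), in liver and colon, with exact 95% Poisson intervals, for lists with at least 4 expected co-detections. Macrophage genes lie at 11.1 in liver and 1.15 in colon.

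A scan of single genes asked which liver genes lay nearer the pericentral or the periportal list. Among 7973 genes, 23 were on the pericentral side and 36 on the periportal side by at least 1 on the log2 scale. A single draw of counting noise alone gave 12 and 16. The named pericentral genes were Fcho2, Cyp2a4, Sntb2, Hhla1, Srd5a3, Atm, Ogfr, Gm14064, Nck1 and Alg6, and the named periportal genes were Gm5424, Fam129b, Ski, Ifngr1, Osbpl3, Extl3, Agk, B230219D22Rik, Thumpd3 and Scai. Most of these rested on a single anchor gene. Fcho2 shared 646 barcodes with the pericentral list (ratio 7.78, 7.19 to 8.40), of which 94.3% carried Cyp2e1, and Gm5424 shared 1769 with the periportal list (7.33), of which 95.5% carried Ass1. For 15 of the 20 genes over 60% of the shared barcodes carried 1 anchor gene. When the most abundant gene of each list, Cyp2e1 and Cyp2f2, was left out, 6 genes were on the pericentral side, where noise gave 5. On the periportal side there were 37, where it gave 22. Ass1 stayed in the periportal list, so this count does not show what remains without it. Among genes with at least 100 expected co-detections, the 10 of largest value on each side were measured again without the anchor gene they shared most. This used the barcodes on which the genes and the anchor gene were chosen, so the values describe these genes and test no explanation. On the periportal side the intervals of 9 of the 10 then held 1 or lay below it, among them Gm5424 (0.919), Celf1 (0.933) and Mrpl15 (0.899), and on the pericentral side those of 5, among them Myl12b (1.07), Itgav (1.08) and St6gal1 (0.861). The intervals of the others lay above 1 on these barcodes. Cyp2c50 and Cyp2c54, cytochrome P450 genes, had pericentral ratios of 1.47 (1.40 to 1.55) and 1.58 (1.43 to 1.74), and 1.51 and 1.65 without Cyp2e1. Gulo, the last enzyme of vitamin C synthesis, had 1.49 and 1.37, Cyp4a12b 1.26 and 1.2475, and Mup17 1.32 and 1.29. On the periportal side, the glutathione transferase gene Gsta1 had 1.27, and 1.31 without Cyp2f2. Without Cyp2e1 the pericentral list still held Cyp2c29 and Cyp2c37, of the same family as Cyp2c50 and Cyp2c54. Reads shared between these genes were not separated. The liver scans pooled the barcodes of both mice, so a gene whose level differs between the mice can follow a list without any arrangement in space.

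In the other scans the genes found more often with a list were fewer than counting noise gave. With the liver acute-phase list, 44 of 6919 genes were found at least 0.5 more often on the log2 scale, where noise alone gave 68, and 252 less often, where it gave 192. The named genes ran from Dhx30 (ratio 1.76, 1.24 to 2.42) over Ppme1, S100pbp, Noc2l, Rnf7, Cd68, Dusp22, Atp13a1 and Ndst3 to Tmem127 (1.52, 1.06 to 2.10). In colon, 13 genes were found more often with surface colonocyte genes where noise gave 37, 0 with goblet genes where it gave 36, and 32 with smooth muscle genes where it gave 43. The genes found less often numbered 50, 65 and 121, where noise gave 111, 123 and 155. The leading genes were Gm14635 with colonocyte genes (1.70, 1.55 to 1.86, with 87.4% of its shared barcodes carrying Lypd8), BC030499 with goblet genes (1.41, 0.953 to 2.02) and Ypel4 with smooth muscle genes (1.82, 1.29 to 2.499). The remaining named genes of each list had ratios no higher than these.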

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

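Mitochondrially encoded genes with ribosomal protein genes had a co-detection ratio of 1.01 in liver and 0.998 in colon. This pair lay outside the cell type questions, and its value differed between the tissues by more than counting error. With 1 library per tissue the difference was not tested.

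The barcode sequences listed in both libraries numbered 3347 (Poisson interval 3235 to 3462), which is 0.0223% of the liver barcodes. Independent draws with the base composition of each library gave an expected 3116, a ratio of 1.07. The overlap lies outside the comparisons of genes, and its cause was not tested.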

How the results depend on the processing

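Of 795 alternative values for 157 results, 610 stayed the same, 170 moved and 15 changed direction. In the tissue comparison 186 of 200 stayed the same, in co-detection 210 of 293, and in the gene scans 214 of 302. The cause was not tested except where a setting's construction gives it.

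TMM scaling changes every CPM ratio by the same factor, which the pseudocount damps for genes of low CPM, so it tests no list. It put the oxidative stress median at −0.17, the mitochondrially encoded median at −0.12 and the ribosomal protein median at 2.02. Without a CPM filter 4793 genes were 4-fold higher in colon and 1963 in liver, and at 10 CPM 2325 were in colon. A pseudocount of 0.1 CPM moved the T cell median to 1.09 and the Paneth median to 0.68. A pseudocount of 10 CPM, which shrinks ratios of low values, gave −5.01 for periportal, −8.06 for hepatocyte, −4.02 for erythroid, 6.33 for goblet, 0.20 for T cell and 0.27 for enteric neuron and glia genes. Leaving out mitochondrially encoded genes, or barcodes under 10 counts, moved no tissue result.

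Without grouping barcodes by total, deep barcodes hold more of every gene, so ratios rise by construction. Pairs past the upper ratio threshold then numbered 52 in liver and 127 in colon, and colon pairs at 0.8 or less 0. Ratios that changed direction were pericentral with periportal (1.23), macrophage with hepatocyte (1.11), major urinary proteins with oxidative stress (1.197), nuclear-retained RNA with hepatocyte (1.06), goblet with smooth muscle (1.59) and surface colonocyte with smooth muscle (1.58). In the scans without grouping, 5 genes were pericentral, where noise gave 10, and 28 periportal, where it gave 9. With acute-phase genes 2245 were found more and 6 less often, with colonocyte genes 17233 and 0, with goblet genes 17436 and 0, and with smooth muscle genes 13891 and 0.

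With products of counts, 12 ratios of single list pairs moved and 3 stayed the same. Pericentral with major urinary proteins changed direction to 0.988, and pairs at 0.8 or less numbered 5 in liver and 5 in colon. With barcodes of 2 to 50 counts, 1 liver pair lay at 0.8 or less, and in colon 1 lay past the upper threshold and 1 at 0.8 or less. Without the most abundant gene of each list, 13 single ratios of pairs and lists moved and 22 stayed the same. Liver pairs at 0.8 or less numbered 2 without the most abundant gene of each list and 1 with totals that leave out mitochondrially encoded genes. In the random parts of the barcodes, which hold fewer counts, liver pairs at 0.8 or less numbered 2 and 1. Colon pairs past the upper threshold numbered 1 and 0, and at 0.8 or less 0 in the second part.

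In the scans, the random parts gave 9 and 10 pericentral genes, where noise gave 5 and 3, and 27 and 17 periportal genes, where it gave 21 and 14. With acute-phase genes, 154 were found less often in the first part, where noise gave 124, and 23 more often in the second, where it gave 37. More often with colonocyte genes were 5 and 7, and with goblet genes 6 and 5, all below the noise counts of 52 and 48, and 53 and 36. Requiring 100 expected co-detections left 0 pericentral and 4 periportal genes. Without the most abundant anchor gene, 6 genes were pericentral, where noise gave 5, and 37 periportal, where it gave 22. In the periportal list that gene was Cyp2f2, and Ass1 stayed in. In this setting 23 were found more and 101 less often with colonocyte genes, and 15 more often with goblet genes. Each of these lay below its noise count of 48, 125 and 37. Directions then changed for Atm (−0.0022), Gm17606 (−0.0604) and 4930429B21Rik (−0.0964). An added alternative, chosen after the data were seen, left out for each named gene the anchor gene it shared most barcodes with. It changed direction for Atm (−0.11), B230219D22Rik (0.28) and Thumpd3 (0.051).

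Spliced-only counts and the unspliced share were not run. No paired analysis was possible because the labels pair no colon with a liver by mouse, and leaving out a library was not possible with 1 per tissue. Depth limits the scans: with a median of 3 counts per liver barcode, 1982 of 7973 genes reached 100 expected co-detections with each list.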

Other observations

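Pairs of genes within the lists, looked at after the list values, showed which partners carried them. In colon, the hormone genes of enteroendocrine L cells shared barcodes: Gcg with Insl5 on 92 where 54.6 were expected (1.68, 1.36 to 2.07), Insl5 with Pyy on 313 (1.64, 1.46 to 1.83) and Gcg with Pyy on 106 (1.61, 1.32 to 1.94). The antibody genes Igha and Igj shared 3281 barcodes where 2072 were expected (1.58, 1.53 to 1.64), and the contractile genes Cnn1 and Tagln 403 where 284 were expected (1.42, 1.28 to 1.56).

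In liver, Cd74 with H2-Aa had a ratio of 13.2 (10.3 to 16.8) and Hba-a1 with Hbb-bs 6.54 (6.03 to 7.08). The pericentral genes Cyp2a5 and Cyp2e1 shared 376 barcodes where 199 were expected (1.89, 1.70 to 2.09). High ratios also joined near-identical genes: Saa1 with Saa2 had 11.1 (9.44 to 13), Orm1 with Orm2 4.80 (4.08 to 5.60) and Mup21 with Mup3 4.18 (3.90 to 4.46). Reads shared between such paralogs were not separated, so these values are uncertain. Orm2 with Saa1, which are not paralogs, had 4.04 (2.80 to 5.64). Differences between the pooled mice were not separated for any of these liver pairs.

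All tests of the contrast between tissues described next were chosen only after the result was seen. Macrophage, MHC class II and fibroblast genes shared barcodes less in colon than in liver. So did nuclear-retained RNA, which marks no cell type (5.07, 3.44 to 7.19, in liver and 1.06, 0.954 to 1.18, in colon). By a smaller margin, so did mitochondrially encoded (1.0345 and 1.0052) and ribosomal protein genes (1.043 and 1.0065). Erythroid genes did not (8.10 in colon, 7.08 in liver), and the intervals of vascular endothelium overlapped. Levels were not matched between the tissues. MHC class II genes summed to 456 CPM in liver and 1847 in colon, fibroblast genes to 402 and 2178.5, and macrophage genes to 621 and 453. In the macrophage list the Kupffer cell genes Cd5l and Clec4f were at least 4-fold higher in liver. A difference in counts per barcode was tested on barcodes of 7 to 10 counts. The macrophage ratio there was 13.7 in liver and 1.19 in colon, MHC class II 15.01 and 1.32, and fibroblast 5.86 and 1.00. The smallest gap between the bounds of the intervals was 3.30-fold. At 4 to 6, 11 to 15 and 16 to 25 counts the liver intervals of these lists also lay above those of colon. The macrophage and fibroblast intervals overlapped at 2 to 3 counts. So did those of fibroblast genes at 26 to 50 (3.06, 0.630 to 8.93, in liver and 1.08, 1.03 to 1.12, in colon). Counts per barcode did not account for the contrast from 4 to 25 counts, and the other ranges cannot tell for every list. An even spread of all RNA over the colon barcodes was tested with alpha and beta globin genes. Their colon ratio was 6.81 (4.04 to 10.8) on 18 co-detections, against 6.81 in liver. The spread was therefore not even for every gene, which leaves the genes of the other lists untested. Erythroid genes summed to 70.8 CPM in colon and 1943.5 in liver, so the equal ratios were not measured at equal levels. A difference between the tissues themselves and a difference between libraries, including the pooling of both mice in the liver library, cannot be told apart with 1 library each, and the macrophage ratio of 1.15 in colon could come from either.

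All tests of the genes of shallow barcodes were chosen only after the result was seen. In liver 99 of 1197 genes took a share at least 2.5 times larger on barcodes with 1 or 2 counts than on the deepest. The deepest were those at or above the 95% quantile of each library, 14 counts in liver and 42 in colon. The ratios of the libraries below therefore rest on unlike depths. Acbd6, at 8627 CPM in liver and 5563 in colon, had ratios of 3.33 and 4.77, Casp12 2.89 and 3.52, and Cntn4 5.47 and 5.90. The genes chosen in liver had a median ratio of 3.77 in colon (interquartile range 2.79 to 5.65, 97 above 1), and other genes 0.941, a recurrence across tissues that is consistent with background not made by the tissue. Of the genes chosen in liver 76.8% were within 4-fold between libraries, against 58.3% of others, and of those chosen in colon 80.4%, against 43.8%. Like levels argue against genes particular to a tissue, by a wider margin for the genes chosen in colon. Genes expressed at like levels in regions of little RNA of both tissues would give the same, so such expression cannot be told apart from background.

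All tests of the genes of the liver zonation scan were chosen only after the result was seen. To avoid measuring genes on the barcodes that selected them, genes and the anchor gene each shared most were chosen in 1 random part of the barcodes and measured in the other. The 10 genes chosen in the first part had a pooled ratio of 12.9 with their anchor gene and 0.923 (0.841 to 1.01) with the rest of its list, and the 13 chosen in the second had 10.3 and 0.983 (0.905 to 1.07). The bounds lay at least 9.28-fold apart, which is consistent with reads of 1 anchor transcript counted under another gene. Expression in the region of the whole list was set against the ratio of the list's own genes. On the periportal side the rest gave 0.859 (0.772 to 0.954) and 0.960 (0.869 to 1.06), where the list's own genes gave 1.07 (1.05 to 1.09). On the pericentral side it gave 1.22 (1.002 to 1.475) and 1.05 (0.895 to 1.22), where they gave 1.36 (1.33 to 1.40). On each side 1 interval lay below that of the list and the other overlapped or held it, so expression in these regions cannot be told apart. Paralogs, overlapping genes, chimeric molecules and differences between the pooled mice were not separated.

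Several marker genes had few or 0 counts. Oat, Trf and Neurod1 had 0 in both libraries, Glul 1.87 CPM in liver, and Clec4g 19 counts in liver. Gapdh stood at 282 CPM in liver and 184 in colon. On barcodes with exactly 2 counts, both came from the same gene on 8.50% in liver and 11.8% in colon, where independence gave 0.863% and 0.282%. Counts of 1 gene were thus not independent, so the intervals of CPM values and fold ratios can be too narrow. The 49 colon barcodes with 200 or more counts held 80609 counts, of which 1.07% were mitochondrially encoded, against 12.5% in the library, and 66.8% came from genes under 50 CPM, against 20.3%. The 3 liver barcodes of that depth held 8120 counts, of which 17.1% were mitochondrially encoded, against 12.5% in the library, and 18.7% came from genes under 50 CPM, against 18.1%. No cause of these values was tested.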
